A study of Mus musculus with 6 samples.

How the data were processed

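Choroid plexus was taken from young C57BL/6J mice, aged 2 to 3 months, and from aged mice of 20 to 22 months, and total RNA was extracted with Trizol, per the labels' protocols. The RNA was labelled with biotin and hybridised to expression arrays at a core facility. There were 6 arrays, 3 per age group, and the labels name a separate mouse for each. The array model and the version of the probe set definition are not given in the sources used here, and neither is the sex of the animals or any batch.

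The authors deposited log2 expression values per probe set, where a probe set gathers the probes of 1 Entrez gene in the Brainarray annotation, per the file headers. The submitters' processing notes name RMA, which corrects background, normalizes between arrays by quantiles and summarises probes on the log2 scale, and limma 3.14.4. The deposited table also holds the authors' signed fold change, a score (the t statistic), p-values and q-values for aged against young, per the file headers. The authors' q-value was given over all probe sets and over a filtered subset. In all 25206 probe sets that subset was the set of probe sets lying above the array median on at least 3 of the arrays. The signed fold in the authors' deposited table matched the ratio of mean linear values within 1 percent in 25206 probe sets, so it can differ in sign from the log2 difference used here. The signs were the same in 24693 probe sets. A value table of the series holds the same log2 values to fewer decimals, with a largest difference of 0.005. The full-precision values were used, and 0 columns of per-sample values were left aside.

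Gene names were updated through the Entrez Gene identifiers to a RefSeq gene table of mouse assembly GRCm38.p6. Of the 25206 probe sets 23740 matched, 2362 of them under another current symbol, and 23 had no symbol in the deposited table. The files name no genome build, so no coordinates are given and the table served only for names and for which genes neighbour each other.

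All probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, with 1 term for age group, no covariate and no filter on dim probe sets. A gene was called where the Benjamini-Hochberg adjusted p was under 0.05. Differences are aged minus young on the log2 scale, errors are SD over the arrays of a group or the moderated standard error (SE), and intervals are at 95%. A total of 40 gene lists (cell type markers and pathways) were fixed before the data were examined and tested with camera, which asks whether a list's genes differ from all other genes, at a preset inter-gene correlation of 0.01. Its p-values are two-sided and adjusted over the 40 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. Member counts are given over all genes and adjusted over the list alone. A list of sex-linked genes served as a check of the animals and stayed out of the adjustment. Of 684 list entries 671 matched a probe set.

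The rule for named genes was fixed before the data were examined. It takes called genes whose 3 aged values all lie on 1 side of the 3 young values, up to 12 per direction by size, and in each list up to 4 called members or, where none was called, the 2 members with the smallest p, given as values. A fixed set of genes known from this tissue and from innate lymphoid cell work is given whatever its values. Not every gene so taken is printed, and results for some list members are not reported here. Other genes named, including those past the first 12 by size, were chosen after their values were seen.

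No detection calls were used. As a guide to background, chosen after the data were examined, the 1350 probe sets of olfactory and vomeronasal receptors had a median of 1.77 and a 95th percentile of 3.52. The mean of 41.7% of all probe sets lay under that percentile. RMA compresses differences near background and near saturation, so folds of very dim or very bright genes are understated. The number of arrays limits the precision of every value.

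The fit was tested on simulated arrays with the means and residual spreads of the 25206 probe sets for aged against young, in 10 runs. It recovered 8.6% of simulated log2 differences of 0.5, 58.8% of those of 1, 92.2% of those of 2 and 99.2% of those of 3, with 4.1 false calls per run. The simulation changed more probe sets than were called in the real data, and no simulated array stood apart. Recovery in the real data may therefore be lower, and the false calls cannot be set against the real count. A list shift of 0.5 was called in 9 of 10 runs, with 0 calls among unshifted lists. That simulation had independent genes, so it says nothing about correlated ones.

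Alternatives were the rounded value table, quantile normalization once more, median centring, filters on dim probe sets, a variance trend with robust eBayes, array weights, the replicate number as a block, leaving out each array in turn, a minimum fold of 1.2 and other thresholds. For lists they also covered an estimated correlation, fry, rank-based camera and lists without shared genes. Leaving out 2 arrays that stood apart was added after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.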

Results

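The choroid plexus, the vascularised epithelial tissue of the brain ventricles that secretes cerebrospinal fluid, was profiled on expression arrays in C57BL/6J mice of 2 to 3 months (young, n = 3) and 20 to 22 months (aged, n = 3). The comparison asked which genes differ in expression between the young and the aged tissue. Array medians lay between 4.03 and 4.10 on the log2 scale, and correlations between arrays ran from 0.982 to 0.990. Correlations were 0.989 to 0.990 among the young arrays and 0.984 to 0.985 among the aged ones. No arrays held identical values. Each array came from a separate mouse, and their number limits the precision of every value. Xist lay between 9.30 and 10.5 on all arrays, while the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty did not exceed 2.51 on any array, within the range of the background guide.

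Aged choroid plexus had higher expression of 15 genes and lower expression of 5 among 25206 probe sets (limma, Benjamini-Hochberg adjusted p under 0.05). The genes that rose were led by the invariant chain Cd74 and the MHC class II chains H2-Aa and H2-Ab1, which present antigen to helper T cells, and by the uncharacterised transcripts 5730507C01Rik and LOC100861711. The genes that fell encode the surface receptor Cdon, the scavenger lectin Colec12, the guidance ligand Sema3e, the matrix protein Abi3bp and the predicted gene Gm10554. For all 20 genes the 3 aged values lay on 1 side of the 3 young values, which their selection by the same values makes likely. Over all probe sets 13.6% showed such separation, where chance gives 10%, and 1959 had an unadjusted p under 0.05, where 1260 would do so by chance.

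Cd74 (probe set 16149_at) rose from 6.02 ± 0.29 to 8.83 ± 0.44 (log2, SD, n = 3 each), a 7.06-fold difference. The log2 difference was 2.82 with a 95% interval of 2.27 to 3.37 (limma adjusted p = 0.0122). H2-Aa (14960_at) rose 6.89-fold, from 5.08 ± 0.27 to 7.86 ± 0.45 (limma adjusted p = 0.0122), and H2-Ab1 (14961_at) 6.13-fold, from 5.57 ± 0.24 to 8.19 ± 0.44 (limma adjusted p = 0.0123). Of the genes that rose, 5730507C01Rik had the largest difference, 3.62 (SE 0.26), from 2.14 ± 0.50 to 5.76 ± 0.31, and LOC100861711, described in the files as similar to a zinc finger protein, rose by 3.40 (SE 0.29) from 2.17 ± 0.04. The young values of both lay in the range of the background guide, so their folds are understated.

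The other genes that rose differed by 0.89 to 1.99 on the log2 scale, with limma adjusted p between 0.0122 and 0.0437. Nyap2, a phosphoprotein adaptor of the phosphoinositide kinase pathway, rose 3.97-fold from 4.93 ± 0.24 to 6.92 ± 0.19. Prom2, a membrane protein of cell protrusions, rose 3.37-fold, and the cytosolic sulfotransferase Sult1c2 rose 3.16-fold, from 7.80 ± 0.25 to 9.46 ± 0.14. Fndc1, which carries fibronectin domains, rose 2.95-fold. The protocadherins Pcdhb1 and Pcdhb22 rose 2.64-fold, from 2.97 ± 0.16, and 2.10-fold, from 4.10 ± 0.10, Pcbd1, an enzyme of pterin recycling, 2.37-fold, and the homeobox gene Dlx4 2.19-fold. The rest were Gm9158, with a 1.95-fold difference from 3.15 ± 0.05, and Pcgf1, a Polycomb group protein, which rose 1.85-fold from 7.77 ± 0.07 to 8.66 ± 0.02. The young values of Pcdhb1 and Gm9158 also lay under the background guide, so their folds are understated too. Sult1c1, in the same region of the genome as Sult1c2 with another gene between them, was higher by 3.42 without passing (adjusted p = 0.122).

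Cdon fell by 1.85 on the log2 scale, from 6.75 ± 0.27 to 4.90 ± 0.29 (SE 0.19, limma adjusted p = 0.0242), and Colec12 fell by 1.74, from 7.43 ± 0.15 to 5.69 ± 0.42 (limma adjusted p = 0.0445). Sema3e fell by 1.66, Abi3bp by 1.56 and Gm10554 by 1.06 (limma adjusted p = 0.0272, 0.0340 and 0.0242). The aged mean of Sema3e, 3.37, lay under the background guide, so its difference is understated. The endopeptidase Mme, chosen after its values were seen, was lower by a log2 difference of -2.19 without passing (adjusted p = 0.0715). In the authors' deposited table the q-value over all probe sets was under 0.05 for 15 higher and 5 lower genes, and the q-value over the filtered subset for 16 and 12. The authors' p-values differed from those of the limma fit here by at most 4.5e-13. The equal counts over all probe sets thus repeat the same test and are no separate support.

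**Figure D1:**
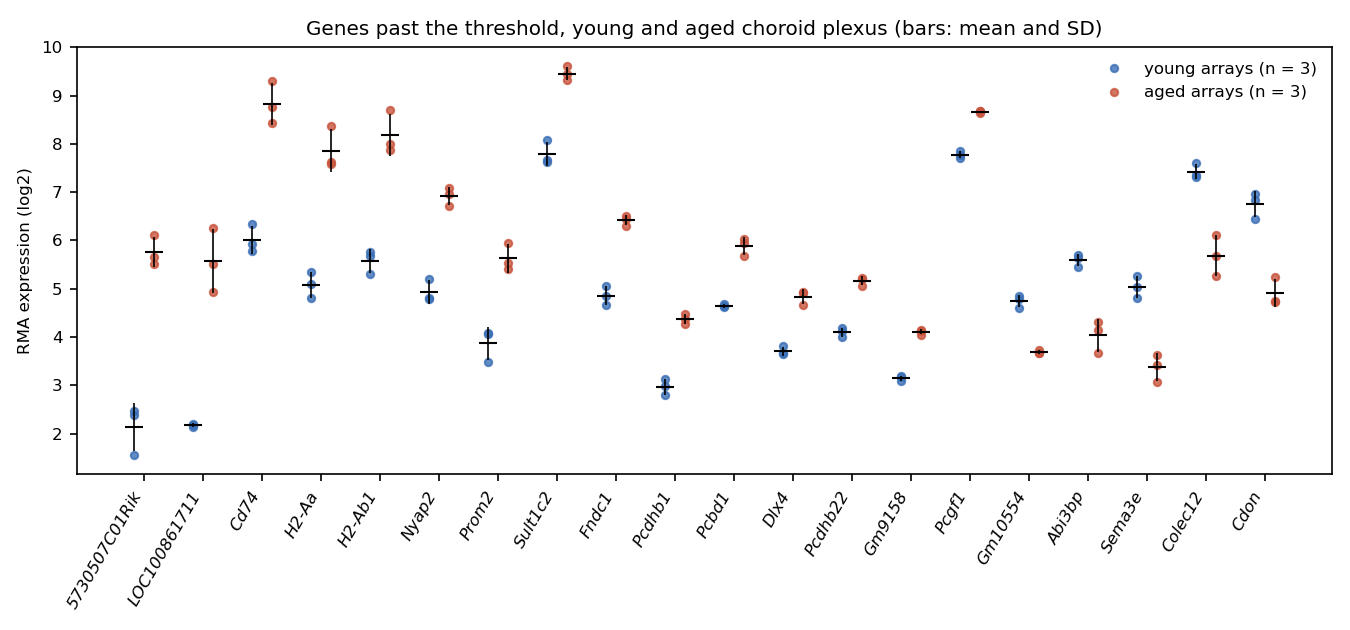
Expression of the 20 genes past the threshold on each array, as log2 values (vertical axis) by gene (horizontal axis), young in blue and aged in red, with group mean and SD. For Cd74 the aged mean of 8.83 stands above the young mean of 6.02.

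These counts changed with single arrays. With limma, higher and lower counts were 2 and 0 without young replicate 1, 6 and 3 without young replicate 3, 27 and 25 without aged replicate 1, and 7 and 1 without aged replicate 3. Both counts were 0 without young replicate 2, when 757 and 746 probe sets had an unadjusted p under 0.05, and 0 without aged replicate 2, when 739 and 823 did.

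Among 40 gene lists, 9 shifted higher and 10 lower in the aged tissue relative to all other genes (camera with a preset correlation, adjusted p under 0.05). None passed with an estimated correlation, where the lowest adjusted p was 0.240 and 5 lists had an unadjusted p under 0.05, and 1 list passed with fry. That correlation was 0.351 for endothelium, 0.475 for MHC class I and 0.939 for oligodendrocytes, but -0.0565 for group 2 innate lymphoid cells. Where it exceeds the preset 0.01, the p-values at the preset may be far too small. When the 6 arrays were split 3 against 3 otherwise than by age, 1 to 14 lists passed at the preset.

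The MHC class II list shifted higher (median log2 difference 0.59, 11 members, camera adjusted p = 7.0e-11; adjusted p = 0.240 with an estimated correlation). Of its members 3 rose over all genes and 6 adjusted over the list alone: Cd74, H2-Aa, H2-Ab1, H2-Eb1, H2-DMa and H2-DMb1. H2-Eb1 was higher by 1.58 (SE 0.26). MHC class I genes, which present peptides to cytotoxic T cells, shifted higher as a list (median 0.39, 15 members, camera adjusted p = 2.3e-08; adjusted p = 0.314 with an estimated correlation), with 0 members called by limma over all genes or adjusted over the list alone and 8 with an unadjusted p under 0.05. H2-D1 stood at 7.09 ± 0.39 in young and 8.17 ± 0.46 in aged, and H2-K1 at 6.03 and 6.59.

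Macrophage markers shifted higher (median 0.52, 19 members, camera adjusted p = 7.5e-05; adjusted p = 0.433 with an estimated correlation). None was called by limma over all genes, while 11 were higher and 3 lower at an unadjusted p under 0.05, and adjusted over the list alone 10 rose and 2 fell. The list mean lay between 4.21 and 4.67 on the young arrays and between 4.66 and 5.17 on the aged ones. Ms4a7 (difference 1.64), Cd68 (1.30), C1qb (1.19), Cd14 (1.13) and C1qc (1.11) were among the higher members, and Pf4 (-0.44) and F13a1 (-0.45), markers of resident macrophages, were the lower. Complement genes shifted higher (median 0.24, camera adjusted p = 0.00693; adjusted p = 0.490 with an estimated correlation). Adjusted over the list alone C1qa, C1qb, C1qc, C3 and C3ar1 rose. The complement list did not pass without young replicate 1 or without genes shared with other lists (camera adjusted p = 0.148 and 0.220), where its mean difference moved from 0.39 to 0.27 and 0.26. The list of activated microglia and macrophages did not pass (median 0.15, camera adjusted p = 0.0510). It passed without young replicate 3, aged replicate 1 or aged replicate 2 (camera adjusted p = 0.0098, 0.00852 and 0.0289), and with arrays centred on their medians (0.0427). Adjusted over the list alone 3 of its members rose, Trem2 by 0.67, Gpnmb by 1.01 and Axl by 0.49.

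Chemokines and inflammatory cytokines shifted higher (median 0.19, 23 members, camera adjusted p = 5.1e-04; adjusted p = 0.314 with an estimated correlation). Adjusted over the list alone 3 rose: Cxcl13, an attractant of B cells, from 3.82 ± 0.46 to 6.91 ± 1.06, Ccl3, higher by 1.07, and Cxcl16, higher by 0.79. T cell markers shifted higher (median 0.27, 15 members, camera adjusted p = 1.7e-04; adjusted p = 0.240 with an estimated correlation), but 9 members had means under the background guide, and among probe sets above the median, with fewer members, the mean difference moved from 0.27 to 0.60 and the list did not pass (camera adjusted p = 0.0612). Limma called 0 members over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. Cd3e stood at 2.98 in young and 3.48 in aged, and Cd8a differed by 0.40. Markers of group 2 innate lymphoid cells, tissue lymphocytes that release type 2 cytokines, shifted higher (median 0.11, mean 0.24, 15 members, camera adjusted p = 0.00129; adjusted p = 0.240 with an estimated correlation). It was the list that passed with fry (adjusted p = 0.0237). None of its members was called by limma over all genes or adjusted over the list alone, 5 had an unadjusted p under 0.05, and 7 had means under the background guide. Gata3 stood at 3.89 ± 0.24 in young and 4.35 ± 0.24 in aged, and Kit at 5.60 ± 0.56 and 6.61 ± 0.45. Kit overlapped between the groups, with 6.24 on young replicate 3 and 6.18 on aged replicate 1. Il7r stood at 2.02 in young and 2.42 in aged, and Klrg1 at 1.91 and 2.25. Both Il7r and Klrg1 lay under the background guide in young and aged. Il1rl1, Il5 and Il13 lay at 2.17, 2.54 and 3.21 in young and 2.28, 2.58 and 3.24 in aged, all within the background range.

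B and plasma cell markers did not pass (median 0.25, camera adjusted p = 0.181). They passed without aged replicate 1 and among probe sets above the median (camera adjusted p = 0.0146 and 0.0346). Their mean difference, 0.61, moved to 0.85 and 2.35 in those settings, the latter with fewer members. Without aged replicate 3 it moved to 0.18. Ighm and Igkc were at 9.58 and 11.35 in aged replicate 3 and no higher than 5.90 and 7.83 on the other arrays. On aged replicates 1 and 2 Ighm was at 5.90 and 5.49 and Igkc at 7.52 and 7.83. The young arrays did not exceed 4.88 for Ighm and 6.92 for Igkc. Natural killer cells (median 0.07, camera adjusted p = 0.645), dendritic cells (0.00, 0.650), neutrophils (0.04, 0.512) and mast cells (-0.02, 0.886) did not pass. In the neutrophil list 1 member rose adjusted over the list alone, Lcn2, an iron-binding acute phase protein also made by other cells, which stood at 4.31 ± 0.52 in young and 6.23 ± 0.99 in aged. Type 2 immunity (median 0.05, camera adjusted p = 0.328) and leukocyte adhesion (0.13, 0.134) did not pass. The adhesion receptor Icam1 stood at 4.47 ± 0.14 in young and 5.05 ± 0.28 in aged (limma adjusted p = 0.437). Il33 was at 5.47 and 5.51, and Ccl11 at 3.23 and 3.19.

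Type I interferon response genes did not shift (median 0.01, 30 members, camera adjusted p = 0.645), and neither did interferon-gamma-induced genes (0.10, 0.0790). Without aged replicate 3 the type I list shifted lower (mean -0.22, camera adjusted p = 8.8e-04), and without young replicate 3, aged replicate 1 or aged replicate 2 the interferon-gamma list shifted higher (camera adjusted p = 0.0462, 0.00333 and 0.0159). Without aged replicate 3, where the interferon-gamma list mean was 4.54, the highest of the 6 arrays, its mean difference was -0.06 (camera adjusted p = 0.540). Over the fits without 1 array the type I mean ranged from -0.22 to 0.09. Irf7, a regulator of interferon induction, stood at 4.15 ± 0.12 in young and 4.15 ± 0.36 in aged. Ifi27l2a and Cmpk2 differed by -0.67 and -0.34, and Cxcl9 and Cxcl10 by 0.46 and -0.06. Ifnb1 and Ifng lay at 1.82 and 2.28 in young and 2.00 and 2.40 in aged, within the background range.

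Endothelial markers shifted lower (median -0.68, 15 members, camera adjusted p = 2.5e-12; adjusted p = 0.240 with an estimated correlation). None fell by limma over all genes, 10 had an unadjusted p under 0.05, and the same number fell adjusted over the list alone. Plvap, a component of fenestral diaphragms, stood at 5.50 ± 0.08 in young and 4.82 ± 0.06 in aged, Podxl at 5.76 and 5.08, the adhesion molecules Pecam1 at 6.19 and 5.36 and Cdh5 at 6.35 and 5.49, and the receptor Kdr at 6.73 and 6.00. The list mean lay between 4.97 and 5.46 on the young arrays and between 4.67 and 4.76 on the aged ones.

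Stromal fibroblast markers (median -0.46, 14 members, camera adjusted p = 6.8e-05; adjusted p = 0.377 with an estimated correlation), collagens and their processing enzymes (-0.36, 25 members, 1.1e-04; adjusted p = 0.314) and mural cell markers (-0.36, 11 members, 0.00381; adjusted p = 0.377) shifted lower. Limma called 0 of their members over all genes, with 5, 11 and 2 lower at an unadjusted p under 0.05. Adjusted over the list alone no fibroblast marker, 5 collagen-list members (Col4a1, Col4a2, Serpinh1, Loxl2 and Sparc) and the pericyte marker Rgs5 fell. Col1a2 stood at 6.87 ± 0.38 in young and 6.21 ± 0.35 in aged. The fibroblast list mean was 6.18 on young replicate 3 and at most 5.45 on the other arrays, and without that array its mean difference moved from -0.48 to -0.21 (camera adjusted p = 0.0367). Without the same array the mean difference moved from -0.28 to -0.17 for the collagen list and from -0.37 to -0.20 for the mural list (camera adjusted p = 0.00325 and 0.0474). Without aged replicate 3 the mural list did not pass (camera adjusted p = 0.0645).

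**Figure D2:**
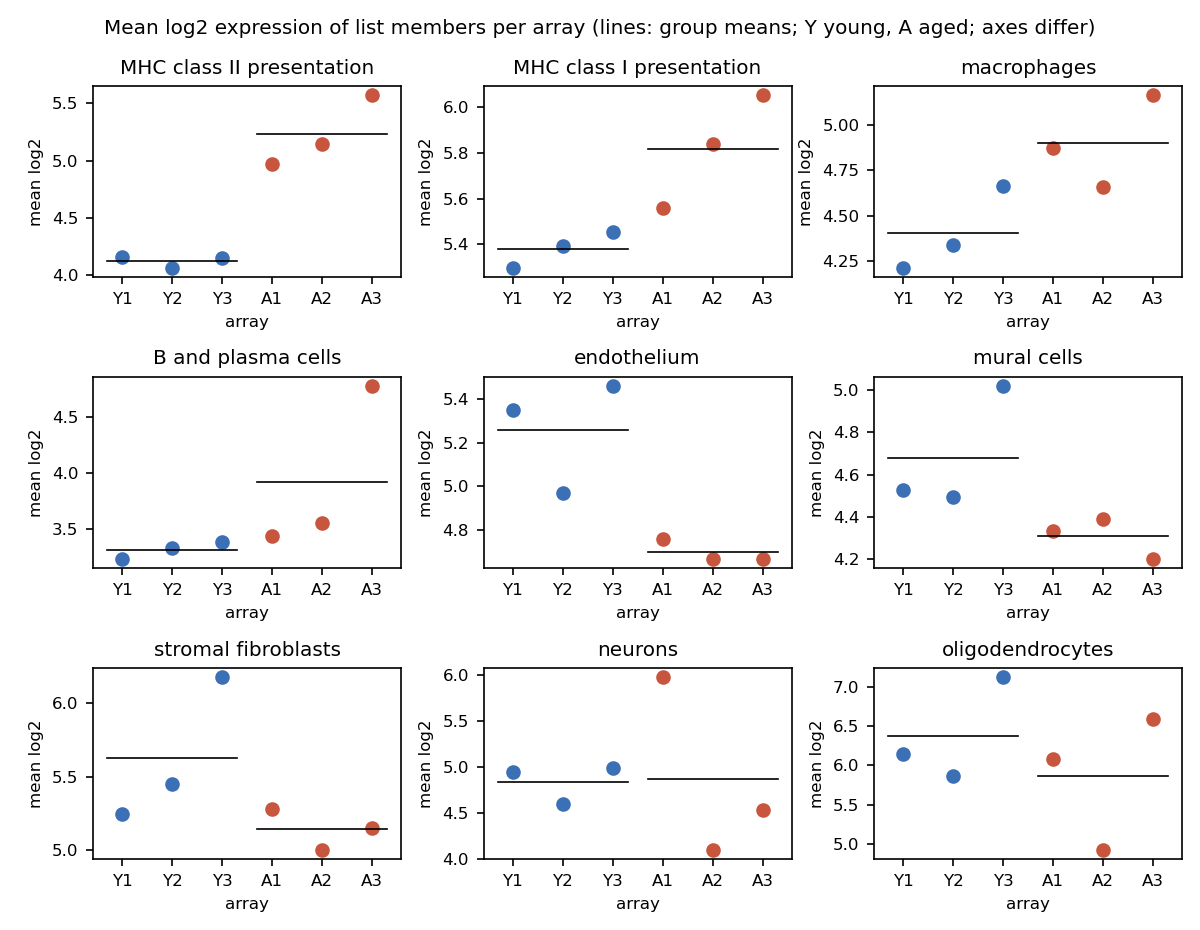
Mean log2 expression of the members of 9 gene lists on each array (Y1 to Y3 young, A1 to A3 aged), with lines at the group means. MHC class II means are higher on the aged arrays, endothelium means are lower, and young 3 has the highest fibroblast mean (6.18).

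Markers of the choroid plexus epithelium did not shift (median 0.05, 20 members, camera adjusted p = 0.645), and neither did ion and water transport (0.01, 0.992), solute and metal carriers (0.00, 0.650) or junction genes (-0.06, 0.392). The list mean for the epithelium lay between 10.67 and 10.92 on every array. Transthyretin, Ttr, the main secreted protein of this epithelium, was at 12.13 on young replicate 1 and between 13.29 and 13.32 on the others. The highest value of any probe set was also 12.13 on young replicate 1 and 13.29 to 13.32 on the others. Enpp2 was likewise at 12.08 there and between 13.01 and 13.04 elsewhere. The scale ended lower on that array, so these values do not show a Ttr difference in that mouse. On the other arrays Ttr and Enpp2 also lay at or near the top of the scale, with aged SDs of 0.01 and 0.02. A change with age in either gene could therefore go unseen, and differences of other very bright members may be understated. Kl, which encodes the aging-related protein Klotho, stood at 11.78 ± 0.24 in young and 11.91 ± 0.10 in aged, and Igf2 at 10.88 and 10.90. Members with the smallest p were Kcne2 (-0.39), Ecrg4 (-0.21), Slc4a2 (0.24), Slc6a15 (-0.57), Slc16a8 (0.79), Jam3 (-0.85) and Cldn1 (-0.44). Adjusted over the list alone, 2 junction genes fell, Jam3 and Cldn1. Signs of median, mean and test differed for junctions (mean 0.01), ion and water transport (mean -0.01, test higher), type I interferon (mean -0.04, test lower), dendritic cells (mean -0.04, test lower) and neurons (mean 0.03, test lower), none of which passed.

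Cholesterol synthesis genes shifted higher (median 0.31, 20 members, camera adjusted p = 5.1e-06; adjusted p = 0.314 with an estimated correlation). Limma called 0 of them over all genes or adjusted over the list alone, and 7 were higher at an unadjusted p under 0.05. Fdft1 stood at 8.88 ± 0.11 in young and 9.30 ± 0.02 in aged, whereas Hmgcs1, an early enzyme of the pathway, differed by -0.17. Unfolded protein response and heat shock genes shifted lower (median -0.12, mean -0.24, camera adjusted p = 2.7e-04; adjusted p = 0.377 with an estimated correlation), with Hspa1a, Hspa1b, Creld2 and Dnajb11 falling adjusted over the list alone. Growth factors and their binding proteins shifted lower (median -0.08, mean -0.22, camera adjusted p = 0.00518; adjusted p = 0.314 with an estimated correlation). In that list Igfbp3, Igf1, Igfbp4 and Bmp5 fell adjusted over the list alone, by 0.68, 0.82, 0.57 and 0.91. That list did not pass without young replicate 3 or aged replicate 3 (camera adjusted p = 0.188 and 0.0645). Glucocorticoid response genes shifted lower (median -0.20, camera adjusted p = 0.00477; adjusted p = 0.240 with an estimated correlation), where Cdkn1a fell adjusted over the list alone, by 0.71, and the list did not pass without young replicate 3 (camera adjusted p = 0.0924).

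Shifts were also called for erythroid genes (median -0.28, 7 members, camera adjusted p = 0.0214; adjusted p = 0.508 with an estimated correlation), motile cilia genes (-0.08, 0.0416; adjusted p = 0.377) and circadian clock genes (0.08, 0.0467; adjusted p = 0.314). The erythroid list did not pass without young replicate 2, young replicate 3, aged replicate 1 or aged replicate 3 (camera adjusted p = 0.195, 0.188, 0.0988 and 0.154). The cilia list did not pass without young replicate 3, aged replicate 2 or aged replicate 3 (camera adjusted p = 0.188, 0.307 and 0.109), nor the clock list without young replicate 1, young replicate 2, aged replicate 1 or aged replicate 3 (0.375, 0.104, 0.0565 and 0.232). The mean difference for erythroid genes, -0.34, moved to -0.16 without young replicate 2 and -0.61 without young replicate 1. For cilia genes, -0.12, it moved to -0.06 without aged replicate 2 and -0.18 without aged replicate 1, and for clock genes, 0.12, to 0.06 without young replicate 1 and 0.20 without young replicate 3. With all arrays the cilia list did not pass after quantile normalization, among probe sets above the median or the lowest quartile, or with array weights (camera adjusted p = 0.0602, 0.110, 0.0611 and 0.121), with means of -0.11, -0.11, -0.12 and -0.08. The erythroid list did not pass with either filter (camera adjusted p = 0.448 and 0.0798, means -0.14 and -0.39). The clock list did not pass above the lowest quartile or with rank-based camera (0.0611 and 0.0721), with its mean at 0.12 in both. Rsph1 differed by -0.45, and the clock-related repressor Bhlhe40 by 0.61. Oligodendrocyte markers shifted lower (median -0.55, 11 members, camera adjusted p = 0.0159; adjusted p = 0.672 with an estimated correlation), but limma gave 0 members an unadjusted p under 0.05, and the list did not pass without young replicate 3 or aged replicate 2 (camera adjusted p = 0.646 and 0.861). Their mean difference, -0.52, moved to -0.14 and -0.04 in those fits and to -0.88 without aged replicate 3, and with array weights the list did not pass (mean -0.37, camera adjusted p = 0.0827). Their list mean was 7.13 on young replicate 3 and 4.92 on aged replicate 2. Neurons (median 0.01, camera adjusted p = 0.981) and astrocytes (-0.07, 0.992) did not pass. Without aged replicate 1 both shifted lower (means -0.53 and -0.53, camera adjusted p = 1.9e-06 and 0.0191), and without aged replicate 2 astrocytes shifted higher (mean 0.32, camera adjusted p = 0.0289). Over the fits without 1 array the neuron mean ranged from -0.53 to 0.41. The neuron list mean was 5.98 on aged replicate 1 and between 4.09 and 4.99 on the other arrays, with Snap25 at 10.6 there and no higher than 8.44 elsewhere.

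Oxidative phosphorylation (median -0.05, camera adjusted p = 0.285), cytosolic ribosomal proteins (0.05, 0.356), cell cycle (-0.05, 0.351), senescence (0.00, 0.588) and immediate early genes (-0.07, 0.696) did not pass. Oxidative phosphorylation shifted lower without young replicate 1 (mean -0.15, camera adjusted p = 7.8e-05), and over the fits without 1 array its mean ranged up to 0.03. In the senescence list Cdkn1a, a cell cycle inhibitor, and Igfbp3 were the members lower adjusted over the list alone.

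**Figure D3:**
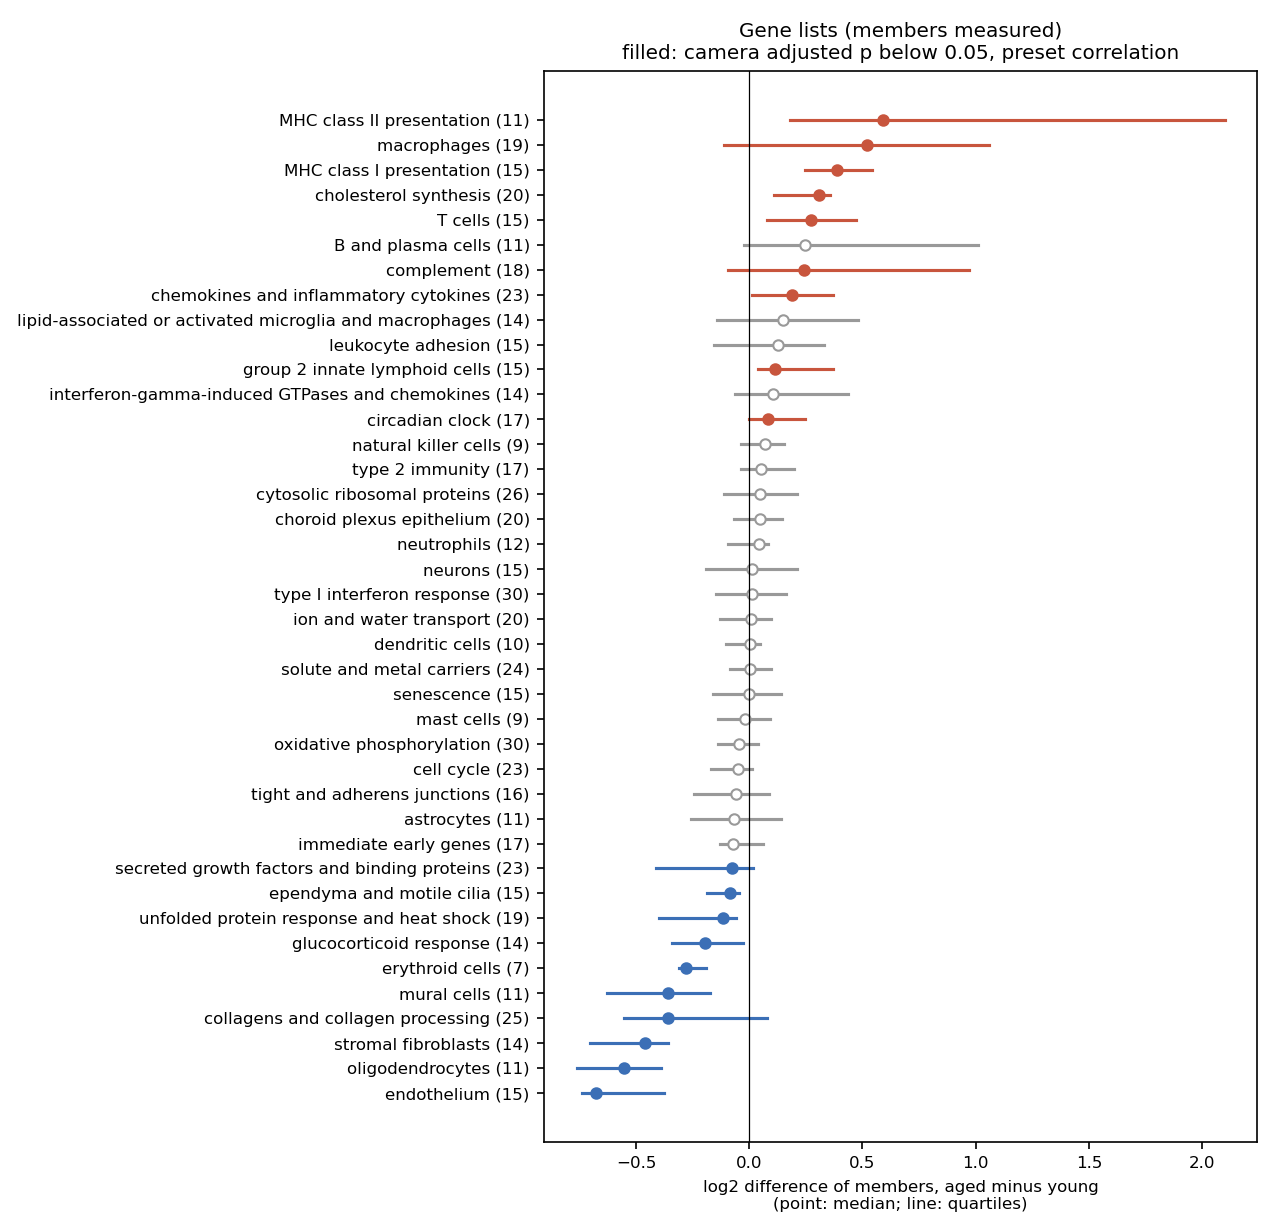
Log2 difference (aged minus young, horizontal axis) of the members of each gene list: points mark medians, lines quartiles, and filled points the lists past the threshold with the preset correlation. The endothelium median of -0.68 is the lowest and the MHC class II median of 0.59 the highest.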

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

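The added setting without 2 arrays was chosen after the data were examined; the others before. All 20 called genes kept their direction in every alternative run before that, and the smallest difference was 0.852, but 0 of them were called in all 6 fits that left out an array. Counts of genes higher and lower in aged ranged from 0 to 27 and from 0 to 25 over those fits, with fewer samples in each. Higher and lower counts were 15 and 8 with quantile normalization or median centring, 12 and 8 among probe sets above the median (11 and 5 shared with the 20), 15 and 10 above the lowest quartile, 17 and 11 with a variance trend, and 15 and 7 with array weights (15 and 4 shared). A minimum fold left 9 and 1. Other thresholds gave 21 and 17 at an adjusted p under 0.1, 63 and 49 at 0.25, 962 and 997 at an unadjusted p under 0.05, and 59 and 44 at 0.001. Without young 3 and aged 1 together they were 27 and 15, of which 10 and 4 were among the genes called on all arrays. The cause of these changes was not tested. Genes removed by a dim-probe filter have no value under it. Over all settings 69 list results lost the call, 20 gained it and 626 did neither; for named genes 101 lost it and 1 gained it.

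The replicate number as a block gave 14 higher and 1 lower, 10 and 1 of them among the genes called without it, and 20 lists, the added one being activated microglia and macrophages. Deviations of same-numbered arrays from their group means had correlations of -0.02, 0.15 and -0.05. Of the 6 arrays 2 correlated best with their own number, as many as chance would give. These values give no sign that the numbers pair the samples, but so few arrays cannot exclude it.

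The 19 list shifts went to 0 with an estimated correlation and 1 with fry; over the other alternatives, including the fits without an array, 15 to 22 lists passed. In all 6 of those fits 11 of the 19 passed, and none passed in the opposite direction. With all arrays and apart from those tests, the cilia list lost the call in 4 settings, the erythroid and clock lists in 2 each, and T cells, oligodendrocytes and complement in 1 each. Several lists, T cells and innate lymphoid cells among them, hold members near background, where array signal limits what can be seen.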

Other observations

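All tests in this part were chosen after the values were seen. In the pathway annotation of the deposited table, 211 sets were tested with camera at the preset correlation, and 16 passed higher and 3 lower, 0 of them with an estimated correlation, where 5 of all sets had an unadjusted p under 0.05. The higher sets included steroid biosynthesis (median 0.27, 18 members, adjusted p = 0.00179; unadjusted p = 0.0394 with an estimated correlation) and lysosome (0.10, 121 members, 0.00187; 0.178), neither of which holds genes of the MHC lists. Spliceosome genes were lower (median -0.09, 120 members, adjusted p = 0.00553; unadjusted p = 0.157 with an estimated correlation). Of the 22 protocadherin gamma genes 20 were higher in aged (median 0.36; camera p = 4.9e-09, p = 0.0314 with an estimated correlation), among them Pcdhga4 by 0.83 and Pcdhgb1 by 0.87, though limma called 0 of them and 8 had an unadjusted p under 0.05. The beta cluster, which holds the called Pcdhb1 and Pcdhb22, had a median of 0.00. Members of these clusters are close in sequence, so their probes can share signal. Gpx3 was at 9.74 and 9.97 on aged replicates 2 and 3 and at most 7.83 on the other arrays, and Spink8 was at 6.73 and 6.78 there and at most 3.70 elsewhere.

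Cd74, H2-Aa and H2-Ab1 rose by 2.62 to 2.82. Cells as rich in immunoglobulin as those of aged replicate 3 do not carry the rise in the other aged samples. As a share of the linear rise on aged replicate 3, the 3 genes reached 53.0% and 57.2% on aged replicates 1 and 2. Ighm and Igkc reached 4.04% and 3.91% there, a ratio of at least 13.1. Both still lay above every young array on aged replicates 1 and 2, so class II-bearing cells with less immunoglobulin RNA are not excluded. A larger number of macrophages of unchanged kind would raise their markers as much. The 95% bootstrap interval of the macrophage median, 0.06 to 1.01, ended below 2.09, the smallest lower confidence limit of the 3 genes. That interval resamples marker genes, not mice. The 3 genes were also picked because they passed the threshold, while the median of the whole class II list was 0.59. The markers thus rose less than these 3 genes, but a larger macrophage share is not excluded. A change in the state or subtype of antigen-presenting cells with age stays open and was not tested; with C1qb and Ms4a7 higher and Pf4 and F13a1 lower, a shift among macrophage subtypes may be part of it.

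The endothelial list mean was lower on every aged array than on any young one. The age difference of its mean was -0.562. With the mean of the neuron, astrocyte and oligodendrocyte lists as a covariate it was -0.530 (SE 0.149, upper 95% bound -0.06). That argues against brain tissue carried over in proportion to this covariate as the whole source. The lists in the covariate did not move together, however: neurons were highest on aged replicate 1 and oligodendrocytes on young replicate 3. With so few arrays, carried-over tissue of another make-up is not excluded. A smaller share of all vascular and stromal tissue is not excluded as the source of the endothelial difference. The endothelial median minus the pooled mural and fibroblast median of -0.41 was -0.272. Its 95% bootstrap interval, -0.377 to 0.109, included 0, but it resamples marker genes, not mice. Without young replicate 3, the mural and fibroblast median was -0.19 and the endothelial one -0.63. The comparison thus depends on 1 array and cannot decide the question. A fall in endothelial content or expression with age stays open as a hypothesis.

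Genes beside those that rose tended to be higher too. For 14 of the 15 with a position in the reference table, 18 of 24 uncalled neighbours were higher (mean 0.27). A share of 5.0e-05 of 100000 random draws reached that mean. The draws took single neighbours independently, whereas the 24 flank selected genes in pairs or clusters, so the share does not exclude random adjacency. On chromosome 12, 5730507C01Rik (3.62), Gm9158 (0.96), Gm5784 (1.12) and 1700030C10Rik (0.78) stood side by side, between genes that differed by 0.11 and -0.01. Shared probes between related genes cannot be told apart from a regional change: leaving out related names and overlaps gave a share of 4.0e-04, but also leaving out MHC pairs and pairs of predicted genes gave 0.039 for 15 neighbours, with a mean of 0.115, inside the central 95% of draws. Of the 2 exclusion rules the wider was adopted after the narrower was seen to keep such pairs. A regional change may exist and was not tested with probe-level data.

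The real split gave 20 genes and the highest of the other splits 0; for lists these were 19 and 14. In each case 1 of the 10 splits of the 6 arrays, the real one, gave as many, and 10 splits are too few for a share under 0.05.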
